A study of Bos taurus with 16 samples.

How the data were processed

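Messenger RNA was measured in whole corpora lutea of cattle, with 4 animals each for day 14, day 17, day 20 and day 23 of pregnancy. Per the labels' protocols, total RNA was extracted with a kit that keeps small RNA, all samples had an RNA quality index above 8.5, and libraries were made with the TruSeq Stranded mRNA kit. The submitters' processing notes name FastQC, HISAT2 2.1.0, bedtools 2.26.0, featureCounts 1.5.3 and DESeq2 and the genome build ARS-UCD1.2, with no settings and no order. Whether reads were counted with regard to strand is not given in the sources used here.

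The authors deposited 1 table of 27233 genes with RPKM (reads scaled by gene length and by the total of the library) for the 16 libraries, and a p-value and an adjusted p-value per gene in columns whose headers do not name the comparison. 21032 genes had a p-value and 15806 an adjusted one. RPKM divides by gene length and by 1 total per library, so that a few genes that take up more reads lower the values of all others, and no scaling for such shifts is built in.

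The RPKM values of a gene are whole multiples of 1 step per library. From those steps the number of reads behind each value was recovered. Values of 27232 of 27233 genes were whole reads within a tolerance of 0.001. Libraries held 28.7 to 44.6 M recovered reads, with a median of 33.9 M. The 50 highest genes took 16.13% to 19.45% of the reads. Between 12614 and 13012 genes per library reached an RPKM of 1.

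Gene names were taken from the table, where 6813 rows have no symbol and 2769 rows share a symbol with another row. The reference gene table available was of another build (ARS-UCD2.0) and was used for names only, so no coordinates are given. OAS1X, OAS1Y and OAS1Z, the copies of IFITM3 and the class I genes of the bovine major histocompatibility complex (BOLA, BOLA-NC1 and JSP.1) are near-identical copies among which counting can split reads, so their separate values are uncertain.

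Values were analysed as log2(RPKM + 1). A pseudocount of 1 shrinks the fold changes of genes near an RPKM of 1 and below. Genes with an RPKM of at least 1 in at least 4 of the 16 libraries were tested, 13361 in all. The test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with 1 model over all 16 libraries and 12 residual degrees of freedom. Contrasts were each later day against day 14, day 20 against day 17 and day 23 against day 20. A moderated F test took the 3 contrasts against day 14 together, and a linear slope on day was fitted apart. P-values are two-sided and were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. RPKM was used as deposited, with no further scaling. No library was removed. Groups came from the day in the labels.

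37 gene lists, 19 of pathways and 18 of cell type markers, were written before the data were examined, together with the tests, the comparisons and most of the alternatives. Of the 891 genes in them, 842 were found in the table. The 30 lists with at least 5 tested members were compared with all other genes by limma's camera, with its preset correlation of 0.01 between genes and again with a correlation estimated from the data, adjusted over the lists. For each list the members past the threshold were counted over all genes and adjusted over the list alone. The mean of log2(RPKM + 1) over the members of a list gave a score per library. Scores were compared by an exact two-sided permutation test of 4 against 4 libraries, whose 70 regroupings allow no p under 0.0286, and over the 4 days by a permutation F test with 100000 resamples, both adjusted over the 30 lists. After that adjustment a p of 0.0286 passes only if most lists reach it. The adjusted p of the exact test therefore cannot count against a list. The list tests between neighbouring days and the tests on scores were added after the data were seen.

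Genes are named by a rule fixed in advance: the 10 largest rises and falls that pass in each contrast against day 14 and 5 each way between neighbouring days, or where none passes the 5 with the smallest unadjusted p. For each list described, up to 4 members with the smallest adjusted p that pass are named, or where none passes the 2 with the highest mean RPKM. A set of landmark genes of luteal function and interferon response is named whatever their result. All genes past the threshold of the slope are named too, which was decided after the data were seen. Some genes that the rule names are not reported here, and those in the table stay in the tests and counts.

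The alternatives were pseudocounts of 0.1 and 0.5, no filter on low values, a filter on a mean RPKM of at least 5, median-ratio scaling, quantile normalization, a replicate block, array weights, no intensity trend, only the 8 libraries of the days compared, and each library left out in turn. Limma's voom on the recovered reads, a robust estimate of the spread, camera on single lists with each library left out, the counts over a list alone under alternatives, the luteal cell score without OXT and the interferon score without near-identical copies were added after the data were seen. So was a negative binomial likelihood-ratio test on the recovered reads with median-ratio scaling, with the spread of each gene drawn towards a trend over the mean. It was run for the counts of genes and of list members and for the 11 genes with a trend in limma. The test planned for a file of counts was not run.

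The script was tested on simulated data, with reads drawn from a negative binomial with each gene's mean and spread in these libraries, 13373 genes past the filter, and known changes set for day 20 against day 14. It called 78 of 98 genes changed 2-fold (79.6%) and 92 of 100 changed 4-fold (92%). Of 193 genes called, 17 (8.8%) were unchanged, against 11 of 188 (5.9%) with voom. The negative binomial test called 87 and 94 of the changed genes, but 74 of its 268 calls (27.6%) were unchanged genes, and it called 8 in a contrast without changes. Limma called 0 genes in a contrast without changes and 0 of 31 unchanged lists. The simulation set no correlation between the members of a list, so it cannot show how often camera's preset correlation gives false calls. In the real libraries, splits other than the real one called a median of 10 lists for days 17 and 14 (highest 19). The median was 9.5 for days 20 and 14 (highest 18) and 8 for days 23 and 14 (highest 21). The simulated spread follows a model and need not match that of the real cattle. At this depth 1 read per kilobase is an RPKM of 0.0264 in the first library of day 14. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used to read the table, test the scores and draw the plots.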

Results

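Messenger RNA was measured in the corpus luteum, the progesterone-secreting gland that forms in the ovary after ovulation. The 16 cattle were found pregnant and were sampled in groups of 4: on day 14, day 17, day 20 or day 23 of pregnancy. The series asks how mRNA abundance changes over early pregnancy. Libraries held 28.7 to 44.6 M reads, with a mean of 34.6 ± 4.36 M on day 14, 34.3 ± 4.21 on day 17, 34.8 ± 6.88 on day 20 and 33.9 ± 0.97 on day 23 (SD, n = 4). The animals of 1 day were about as alike as animals of different days: the median correlation across genes was 0.975 within a day and 0.972 between days, where genes are not independent replicates. P-values below for single genes and for list scores measure the spread between these 16 cattle. Those of camera with its preset correlation do not, since they take the members of a list as nearly independent. The correlation estimated from the data was far higher in some lists, such as 0.695 for interferon-stimulated genes, 0.743 for T cells and 0.779 for ribosomal proteins. For camera, the values with an estimated correlation are therefore given as well. Errors of RPKM are SD over 4 libraries and errors of log2 fold changes are standard errors on the scale of log2(RPKM + 1).

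The tissue had the profile of a steroid-secreting gland on each day. HSD3B1, which makes progesterone from pregnenolone, had an RPKM of 4826 ± 461 on day 14 and 5832 ± 1021 on day 23, and CYP11A1, which cleaves the side chain of cholesterol, 4424 ± 476 and 4047 ± 289. STAR, which carries cholesterol into mitochondria, had 2339 ± 537 on day 14 and 3559 ± 727.5 on day 23 (log2 fold change 0.61 ± 0.24, adjusted p = 0.31 in limma). SCARB1, the lipoprotein receptor, had 3988 ± 991 and 4203 ± 385. PTGFR, the receptor through which prostaglandin F2 alpha ends luteal life, had 475 ± 116 on day 14, 376 ± 122 on day 17, 395 ± 115 on day 20 and 498.9 ± 110 on day 23. None of the 33 steroidogenesis genes passed in limma on any day, and the list was not called (camera adjusted p = 0.087, 0.11 and 0.66 on days 17, 20 and 23). The mean over 10 markers of large and small luteal cells was 9.09 ± 0.07 on day 14, 8.93 ± 0.09 on day 17, 8.86 ± 0.09 on day 20 and 8.90 ± 0.10 on day 23. On each later day 4 of 4 libraries lay below the 4 of day 14 (exact permutation p = 0.0286 each, adjusted p = 0.51, 0.21 and 0.14). OXT carries much of this: the differences of -0.16, -0.234 and -0.193 were -0.094, -0.113 and -0.023 for the 9 other markers (exact permutation p = 0.057, 0.057 and 0.86). Camera did not call these markers (adjusted p = 0.087, 0.065 and 0.59), and OXT was the 1 member past the threshold over the list alone, on days 20 and 23. The direction of HSD3B1 on day 23 is uncertain, since its log2 fold change of 0.26 becomes -0.05 under quantile normalization. Among the other landmarks, FOS had an RPKM of 37.9 ± 54.3 on day 14 and 20.1 ± 22.4 on day 23, a log2 fold change of -0.59 that is 0.25 without day 14 replicate 4. PGR had 1.34 ± 0.12 on day 14 and 1.29 ± 0.12 on day 23, and VEGFA 150 ± 38.9 and 114.5 ± 27.6. PTGS2 (0.386 ± 0.097 on day 14), HPGD (0.537 ± 0.25) and OXTR (at 0 in the 4 libraries of day 14) were below the filter.

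On day 17, compared with day 14, markers of natural killer and cytotoxic cells were higher in 7 of 7 tested members, where 11 were found in the data. NCR1, an activating receptor of natural killer cells, was at 1.42 ± 0.47 against 0.315 ± 0.26 RPKM, GNLY (granulysin) at 4.50 ± 1.31 against 1.59 ± 1.72, and PRF1 (perforin) at 3.47 ± 0.88 against 1.65 ± 1.09 (n = 4). With GZMA (1.58 ± 0.35 against 0.678 ± 0.27) and KLRK1, 5 of the 7 passed when adjusted over the list alone and 0 over all genes. The day 14 means of NCR1 and GZMA lie below the filter's RPKM of 1. The filter kept them at least in part through libraries of later days, which favours rises. The T cell markers had positive fold changes in 13 of 13 members, among them the kinase LCK with 4.87 ± 1.11 against 3.78 ± 0.80 and CD247 with 4.51 ± 0.78 against 3.19 ± 0.44, and 0 passed. Genes stimulated by interferon had positive fold changes in 40 of 42 members with a mean of 0.54, and 0 passed even over the list alone. The most abundant were LGALS3BP at 500.6 ± 119.6 against 471 ± 44.3 and IFI6 at 340 ± 283 against 161 ± 94.5. The mean of the list in the day 17 libraries was 3.48, 3.54, 4.99 and 4.03, so that replicate 3 lay in the range of day 20 (4.52 to 5.13), and without it the mean fold change was 0.21. ISG15, an interferon-induced ubiquitin-like protein, was at 119 ± 161 against 21.2 ± 7.90, because 1 animal, day 17 replicate 3, had 359.5 and the other 3 had 26.8, 28.4 and 61.3.

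Several metabolic and stress lists leaned the other way on day 17. Genes of cholesterol synthesis and uptake had negative fold changes in 26 of 29 members. HMGCS1, an early enzyme of the pathway, was at 722 ± 230 against 1071 ± 145 and APOA1, the most abundant member, at 3031 ± 890 against 3154 ± 839. Oxidative phosphorylation had negative values in 31 of 34 members (ATP5F1B 613 ± 46.9 against 657 ± 6.77, COX6A1 693 ± 111 against 711 ± 40.1). Immediate early genes had them in 24 of 28 (JUND 102 ± 17.7 against 124 ± 42.5, FOSL2 195.5 ± 31.9 against 203 ± 36.6). For the unfolded protein response they stood in 22 of 29 (HSPE1 293.5 ± 9.24 against 331 ± 9.81, HSP90B1 300.2 ± 52.1 against 285 ± 44.5). No single member of these 4 lists passed over its list alone. The values of immediate early genes rest on day 14 replicate 4, whose score was 5.04 where the others had 3.73 to 3.89. Without it their mean fold change was -0.01 instead of -0.32 and the call ended (camera adjusted p = 0.52). For oxidative phosphorylation the mean of -0.08 was 0.004 without day 17 replicate 4 (0.96) and -0.13 without day 17 replicate 1.

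Camera called 7 lists on day 17 with its preset correlation. Adjusted p was 1.5e-09 for interferon-stimulated genes (adjusted p = 0.53 with an estimated correlation), 1.9e-05 for natural killer cells (0.53 with an estimated correlation), 2.3e-05 for cholesterol (0.53) and 0.00037 for T cells (0.54). It was 0.00037 for oxidative phosphorylation (0.62), 0.00079 for immediate early genes (0.53) and 0.0025 for the unfolded protein response (0.53). None of these calls held with an estimated correlation. By limma, 0 of 13361 genes passed on day 17, with a smallest adjusted p of 0.61. At an unadjusted p under 0.05 there were 1011 genes, 657 higher and 354 lower, voom gave 0 genes and 1080 unadjusted, and a negative binomial test on the reads recovered from the RPKM steps 21 genes and 1456. Among the 5 genes with the smallest p, which did not pass, were EREG (3.65 ± 1.85 against 16.6 ± 7.62 RPKM), HBB (10.4 ± 9.67 against 0.228 ± 0.28), CROCC (11.7 ± 0.73 against 8.62 ± 0.64) and ICAM3 (6.65 ± 0.82 against 3.52 ± 0.91). The count of natural killer genes was 2 without day 14 replicate 2, day 14 replicate 4, day 17 replicate 1, day 17 replicate 3 or day 17 replicate 4, 3 with only the 8 libraries of both days and 0 with a filter on a mean RPKM of 5. The 7 lists became 11 without day 14 replicate 3 or day 17 replicate 2 and 14 without day 17 replicate 3, and without that last library 1 gene passed, HBB. This beta-globin gene, a marker of red blood cells, had 14.9, 4.11, 0.92 and 21.8 RPKM in the day 17 libraries and at most 0.615 in those of day 14.

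On day 20, interferon-stimulated genes were higher than on day 14 in 42 of 42 tested members, and 38 of them passed when adjusted over the list alone. ISG15 was at an RPKM of 196 ± 46.7 against 21.2 ± 7.90 (log2 fold change 3.21 ± 0.64, n = 4). MX1 and MX2, antiviral GTPases, were at 175 ± 42.7 against 44.7 ± 15.5 and at 7.91 ± 5.53 against 0.745 ± 0.19. RSAD2 (viperin) was at 14.1 ± 4.33 against 2.94 ± 1.251 and EIF2AK2, the kinase that senses double-stranded RNA, at 14.7 ± 1.89 against 8.003 ± 1.07. HERC6, a ligase for ISG15, was at 22.9 ± 4.66 against 7.62 ± 1.72, and OAS1Y at 174 ± 51.0 against 31.7 ± 8.92, with reads that near-identical OAS1 copies can share. The mean of the list was 4.77 ± 0.31 against 3.47 ± 0.25, and 4 of 4 libraries of day 20 lay above the 4 of day 14 (exact permutation p = 0.0286, the smallest that 4 against 4 can give, adjusted p = 0.21). Adjusted over the lists, that p passes only if most lists reach it. Camera gave this list an adjusted p of 2.5e-54, with adjusted p = 0.14 with an estimated correlation.

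**Figure D1:**
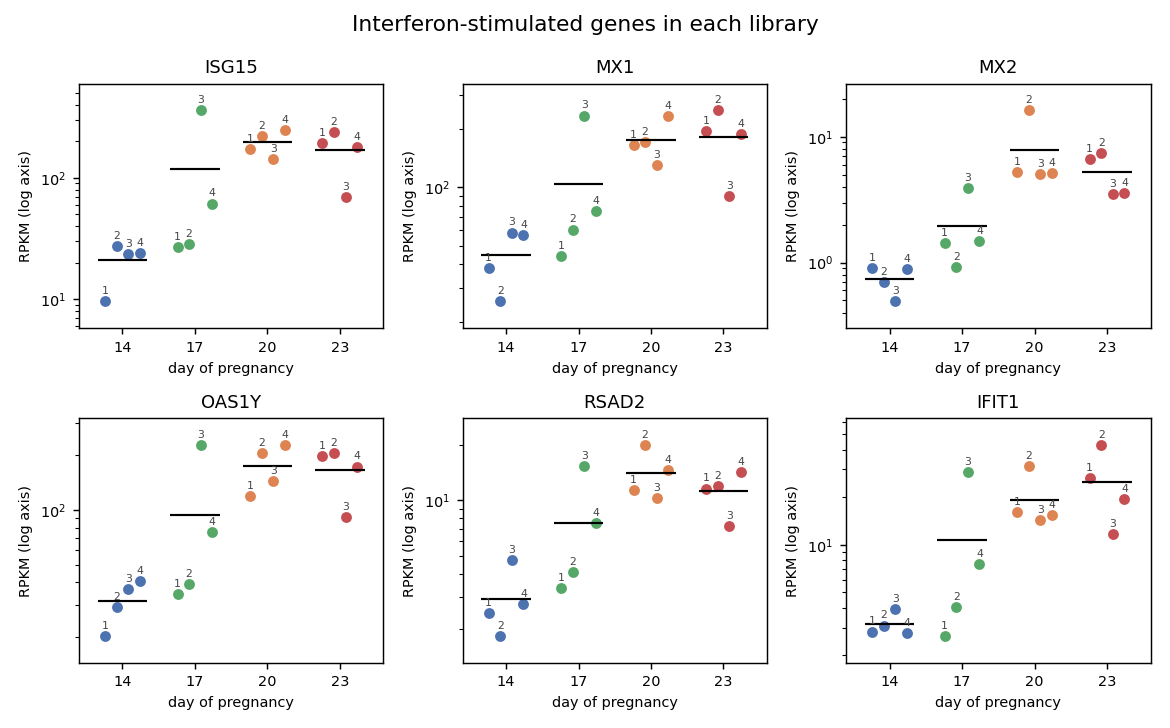
RPKM on a log axis of 6 interferon-stimulated genes against day of pregnancy, with 1 numbered point per library and a bar at the mean of the 4 libraries of a day. For ISG15 the libraries of day 20 have 143 to 247 and those of day 14 have 9.64 to 27.5, and day 17 replicate 3 stands at 359.5, apart from the other 3 of its day.

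Lists of macrophages, natural killer and T cells, antigen presentation and cytokines leaned the same way on day 20, and dendritic cell markers were negative in 4 of 5 members with the list not called (camera adjusted p = 0.75). Macrophage and monocyte markers had positive values in 14 of 15 members, and 5 passed over the list alone. Among them were SIGLEC1 (3.84 ± 0.63 against 1.197 ± 0.37), CD163, a scavenger receptor (24.2 ± 8.74 against 11.6 ± 2.02), C1QB of the complement system (114.5 ± 20.1 against 58.9 ± 9.14) and CD14 (16.04 ± 4.92 against 9.02 ± 2.03). SIGLEC1 itself is induced by interferon. Natural killer markers were positive in 7 of 7 with 4 past the threshold over the list alone (NCR1 1.53 ± 0.66 against 0.315 ± 0.26, GZMA, PRF1 and GNLY). T cell markers were positive in 13 of 13 with 0 past it (LCK 5.01 ± 1.98 against 3.78 ± 0.80, CD247 4.61 ± 1.23 against 3.19 ± 0.44). Antigen presentation had positive values in 26 of 27 members with 0 past the threshold. The most abundant were the class I genes JSP.1 (1232 ± 912 against 669.6 ± 485) and BOLA (822 ± 410 against 255 ± 174), which share reads with other copies. Cytokines and chemokines were positive in 23 of 26 members with 0 past the threshold, such as CCL21 with 354 ± 158 against 284 ± 69.5 and CXCL16 with 54.3 ± 5.10 against 47.5 ± 12.1. Camera gave adjusted p = 1.6e-08 for macrophages, 1.7e-08 for antigen presentation, 2.4e-08 for T cells and 5.2e-06 for cytokines, each with adjusted p = 0.28 with an estimated correlation. It gave 8.8e-08 for natural killer cells, with adjusted p = 0.245 with an estimated correlation.

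Among the other lists on day 20, oxidative phosphorylation had negative values in 32 of 34 members and 0 passed over the list alone (camera adjusted p = 2.3e-11, adjusted p = 0.28 with an estimated correlation). COX6A1 was at 670 ± 37.0 against 711 ± 40.1 and ATP5F1B at 547.5 ± 36.95 against 657 ± 6.77. Cholesterol genes were negative in 26 of 29 (APOA1 2433 ± 599 against 3154 ± 839, HMGCS1 763 ± 259 against 1071 ± 145, adjusted p = 0.0016, and 0.59 with an estimated correlation). Markers of pericytes and smooth muscle were positive in 9 of 14 and 2 passed over the list alone (adjusted p = 0.027, and 0.59 with an estimated correlation). These were MYH11, smooth muscle myosin, at 40.3 ± 13.4 against 20.4 ± 5.58 and LMOD1 at 4.76 ± 1.80 against 2.16 ± 0.52. Fibroblast markers were positive in 11 of 11 (COL1A1 1589 ± 488 against 1157 ± 296, COL3A1 1407 ± 525.5 against 1306 ± 252, adjusted p = 0.012, and 0.53 with an estimated correlation). Immediate early genes were positive in 20 of 28 (FOSL2 171 ± 31.0 against 203 ± 36.6, JUND 155 ± 42.9 against 124 ± 42.5, adjusted p = 0.0047, and 0.53 with an estimated correlation). Cell cycle genes were negative in 26 of 30 (MCM7 16.5 ± 1.27 against 17.2 ± 3.04, PCNA 17.15 ± 2.22 against 15.6 ± 2.40, adjusted p = 0.015, and 0.59 with an estimated correlation). Endothelial markers were negative in 16 of 19 (EGFL7 96.9 ± 23.8 against 121 ± 47.4, RAMP2 100.4 ± 7.80 against 104.9 ± 13.0, adjusted p = 0.024, and 0.59 with an estimated correlation). Ribosomal proteins were negative in 39 of 45 (RPL37 1073 ± 127.5 against 1110 ± 121, RPL23 983 ± 129 against 983 ± 88.6, adjusted p = 0.033, and 0.73 with an estimated correlation).

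The weaker of these calls on day 20 depend on single libraries. The cholesterol call ended without day 14 replicate 1, day 20 replicate 1 or day 20 replicate 4 (adjusted p = 0.066, 0.11 and 0.11), and its mean of -0.25 was -0.37 without day 14 replicate 3 or day 20 replicate 3. The cell cycle call ended without day 14 replicate 1, 2 or 3 (0.12, 0.22 and 0.064) or day 20 replicate 2 or 3 (0.19 and 0.27), and its mean of -0.14 was -0.23 without day 14 replicate 4 and -0.25 without day 20 replicate 1. The ribosomal call ended without day 14 replicate 1 or 3 (0.80 and 0.28) or day 20 replicate 1 or 2 (0.84 and 0.13), and its mean of -0.06 was -0.11 without day 14 replicate 4 and -0.12 without day 20 replicate 4. The endothelial call ended without day 14 replicate 3 or 4 (0.29 and 0.16) or day 20 replicate 1 (0.15), and its mean of -0.145 was -0.22 without day 14 replicate 2. The call of immediate early genes ended without day 14 replicate 2 or 3 (0.068 and 0.15), and their mean of 0.35 was 0.65 without day 14 replicate 4 and 0.21 without day 20 replicate 4. That of fibroblasts ended without day 14 replicate 2 or 4 (0.054 and 0.093) or day 20 replicate 2 (0.11), and that of pericytes without day 14 replicate 2 (0.38) or day 20 replicate 1 (0.37).

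By limma over all 13361 genes, 0 passed on day 20 against day 14, with a smallest adjusted p of 0.14. There were 1084 genes at an unadjusted p under 0.05, 572 higher and 512 lower, voom gave 0 genes and 1075 unadjusted, and the negative binomial test 188 genes (142 higher and 46 lower, 29 on the interferon list) and 1410. The 5 with the smallest p were MX2, ANKRD33B, RSAD2, EIF2AK2 and HERC6, and ANKRD33B was at a mean RPKM of 3.25 against 0.879, a log2 fold change of 1.15. The 0 in limma depends on day 17 replicate 3, whereas it stayed 0 without replicate 1, 2 or 4 of that day. With only the 8 libraries of days 14 and 20, which leaves out days 17 and 23 together, 20 genes passed, 19 higher and 1 lower, and 15 of them are on the interferon list (ISG15, IFIT1, USP18, DHX58 and OAS1Y among those with adjusted p = 0.013). Without day 17 replicate 3, 32 genes passed, 29 higher and 3 lower, 20 of them on that list, and 17 genes were shared by both sets.

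**Figure D2:**
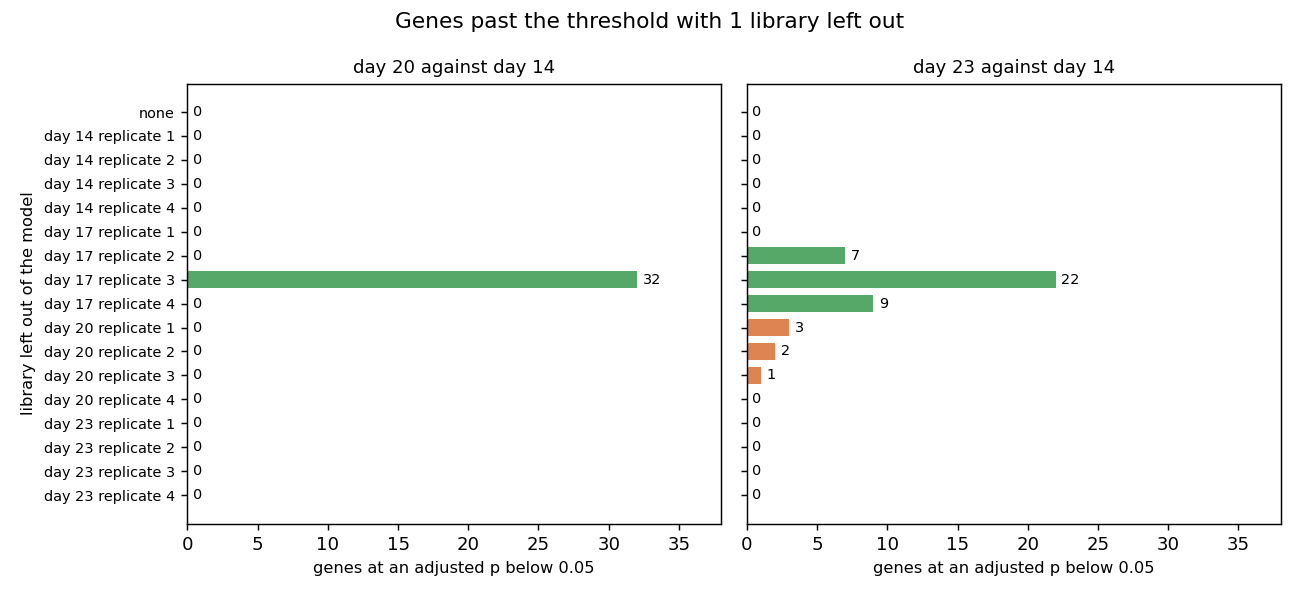
Number of genes at an adjusted p below 0.05 in limma (horizontal axis) when the library named on the vertical axis is left out, for day 20 and day 23 against day 14. The count for day 20 is 0 except for 32 without day 17 replicate 3, and the count for day 23 is highest, at 22, without the same library.

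On day 23, interferon-stimulated genes were again higher than on day 14 in 42 of 42 members, and 36 passed when adjusted over the list alone. IFIT1, an antiviral RNA-binding protein, was at an RPKM of 25.1 ± 13.2 against 3.15 ± 0.54 and OAS1Y at 167 ± 52.5 against 31.7 ± 8.92. MX2 was at 5.28 ± 2.03 against 0.745 ± 0.19, EIF2AK2 at 13.8 ± 1.54 against 8.003 ± 1.07 and HERC6 at 20.4 ± 4.00 against 7.62 ± 1.72. The landmarks ISG15, MX1 and RSAD2 were at 169.5 ± 71.5, 181 ± 66.9 and 11.3 ± 2.90 (n = 4). The mean of the list was 4.59 ± 0.37 against 3.47 ± 0.25, higher in 4 of 4 libraries than in the 4 of day 14 (exact permutation p = 0.0286, adjusted p = 0.14). Camera gave 9.4e-37, with adjusted p = 0.38 with an estimated correlation. The number past the threshold was 24 without day 14 replicate 1, the library with the lowest score of day 14. T cell markers had positive values in 13 of 13 members (LCK 4.43 ± 1.253 against 3.78 ± 0.80, CD247 4.10 ± 0.97 against 3.19 ± 0.44, adjusted p = 0.00018, and 0.67 with an estimated correlation). Natural killer markers had them in 6 of 7 (NKG7 4.93 ± 1.38 against 5.12 ± 1.199, GNLY 2.29 ± 0.80 against 1.59 ± 1.72, adjusted p = 0.0039, and 0.65 with an estimated correlation). In both lists 0 passed. Macrophage markers had positive values in 6 of 15 and the list was not called.

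Cell cycle genes were lower on day 23 in 30 of 30 members, and 20 passed over the list alone. TOP2A, the DNA topoisomerase of dividing cells, was at an RPKM of 1.36 ± 0.70 against 3.70 ± 0.46 and BIRC5 (survivin) at 1.84 ± 0.43 against 3.54 ± 0.39. AURKB was at 1.77 ± 0.55 against 3.61 ± 0.83 and CCNB1 (cyclin B1) at 0.917 ± 0.46 against 2.69 ± 0.54. The mean of the list was lower than on day 14 in 4 of 4 libraries (1.66 ± 0.17 against 2.18 ± 0.17, exact permutation p = 0.0286, adjusted p = 0.14; camera adjusted p = 3.7e-15, and 0.38 with an estimated correlation). These genes are low, and a filter on a mean RPKM of 5, which removes most of them, left 1 past the threshold. Endothelial markers were lower in 19 of 19 members and 7 passed over the list alone. Among them were CDH5, the cadherin of endothelial junctions (46.4 ± 4.17 against 63.9 ± 9.28), ECSCR (12.8 ± 1.04 against 18.9 ± 2.28), RAMP2 (81.2 ± 7.64 against 104.9 ± 13.0) and CLEC14A (48.3 ± 10.1 against 72.8 ± 16.2). Camera gave endothelial markers 1.5e-07, with adjusted p = 0.38 with an estimated correlation. Their count of 7 was 1 without day 14 replicate 3, 3 without day 14 replicate 4, and 4 without day 23 replicate 3 or day 23 replicate 4.

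The lists of angiogenesis and of extracellular matrix also had mostly negative values on day 23. On the angiogenesis list 23 of 30 members had negative values and 3 passed over the list alone. These were the receptors KDR (66.2 ± 5.71 against 96.5 ± 18.7 RPKM) and APLNR (14.4 ± 2.00 against 33.1 ± 14.1) and the hypoxia factor HIF1A (106 ± 16.5 against 170 ± 9.07; camera adjusted p = 0.0097, and 0.77 with an estimated correlation). The call ended without day 14 replicate 4 (0.18). Lymphatic endothelial markers were positive in 3 of 5 and PDPN was higher over the list alone, with the list not called (0.26). Genes of the extracellular matrix were negative in 26 of 37 and 3 passed over the list alone, all collagens of basement membranes. They were COL4A1 (482 ± 84.7 against 784 ± 106), COL4A2 (363 ± 67.3 against 525 ± 65.2) and COL18A1 (139 ± 30.3 against 223 ± 47.3; camera adjusted p = 0.019, and 0.77 with an estimated correlation). The mean fold change of -0.24 was -0.15 without day 14 replicate 3 and -0.09 without day 23 replicate 2, where the call ended (0.14 and 0.57), and -0.37 without day 23 replicate 3. Oxidative phosphorylation was negative in 31 of 34 with COX5A past the threshold over the list alone (87.1 ± 7.32 against 112 ± 7.56; 2.3e-07, and 0.65 with an estimated correlation). Ribosomal proteins were negative in 43 of 45 with 0 (RPL37 1001 ± 135 against 1110 ± 121, RPL23 872 ± 99.4 against 983 ± 88.6; 0.00012, and 0.77 with an estimated correlation). The unfolded protein response was negative in 22 of 29 and 2 passed over the list alone (0.032, and 0.67 with an estimated correlation). These were HSPE1 (235 ± 7.57 against 331 ± 9.81) and 1 of 2 genes with the symbol HSPD1 (89.85 ± 2.885 against 124.7 ± 14.1), chaperonins of the mitochondrial matrix and not of the endoplasmic reticulum. Its call ended without day 14 replicate 1, 2 or 4 (0.11, 0.073 and 0.098) or day 23 replicate 1 or 4 (0.37 and 0.25). The ribosomal call ended without day 14 replicate 1 (0.087) or day 23 replicate 2 (0.065).

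By limma over all genes, 0 of 13361 passed on day 23 against day 14, with a smallest adjusted p of 0.055. There were 1679 genes at an unadjusted p under 0.05 (12.6%), 576 higher and 1103 lower, voom gave 0 genes and 1628 unadjusted, and the negative binomial test 518 genes (220 higher and 298 lower, 25 on the interferon list) and 2114. The 5 with the smallest p were HSPE1, EREG, an epidermal growth factor family ligand (1.76 ± 0.66 against 16.6 ± 7.62 RPKM, adjusted p = 0.063), CITED4 (50.9 ± 14.3 against 110.4 ± 20.1), FAM167B (6.06 ± 2.08 against 15.5 ± 0.45) and ACSM1 (54.2 ± 17.5 against 19.7 ± 4.23). The 0 in limma depends on the libraries of other days, since 13 genes passed with only the 8 libraries of days 14 and 23 (7 higher and 6 lower). There were 22 without day 17 replicate 3, 9 without day 17 replicate 4, 7 without day 17 replicate 2, 3 without day 20 replicate 1, 2 without day 20 replicate 2 and 1 without day 20 replicate 3. Of the 22, 12 are on the interferon list, and 8 genes were shared with the 13, EREG, FOSL1, MX2, OAS1Y, IFIT1, DHX58, DDX58 and HERC6.

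**Figure D3:**
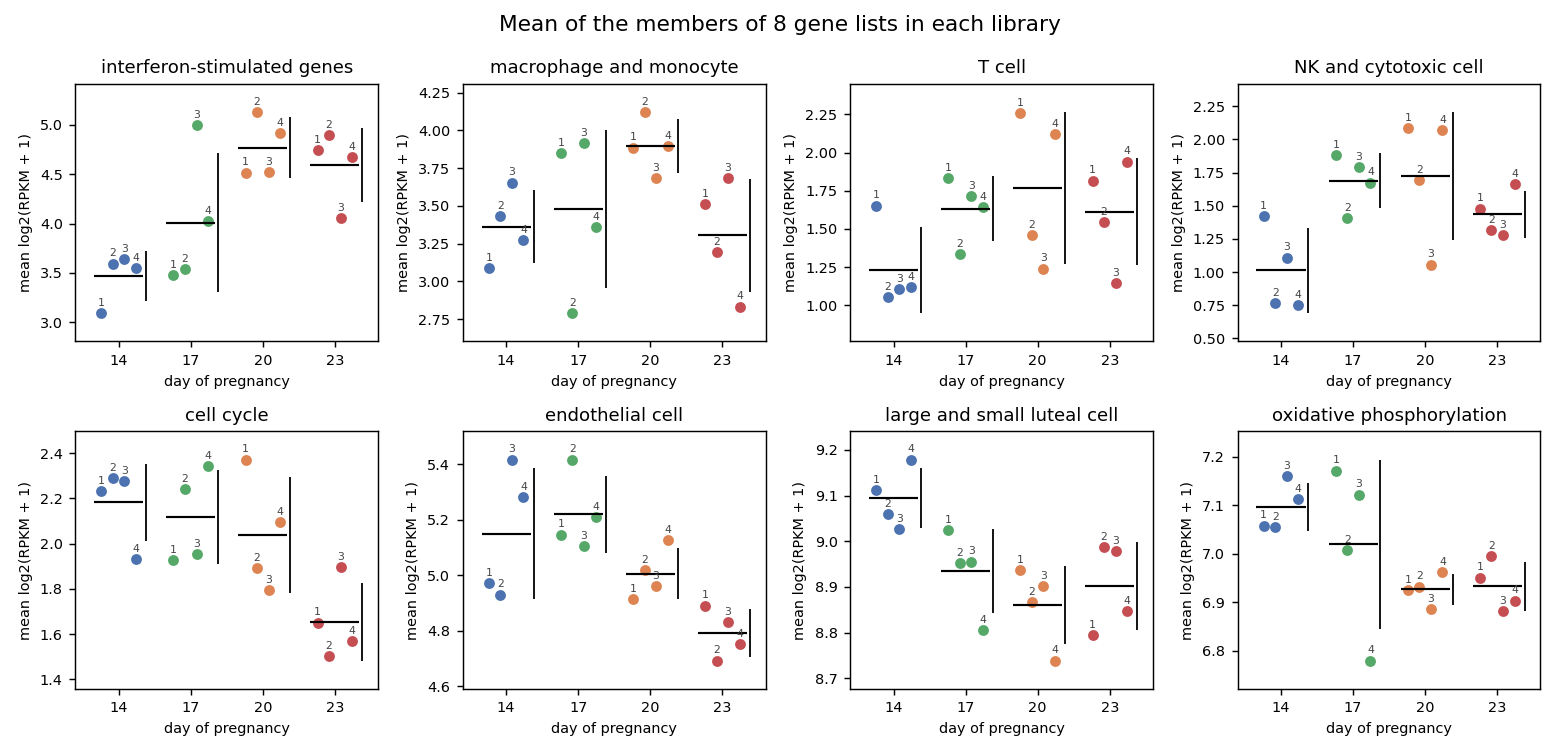
Mean log2(RPKM + 1) of the members of 8 gene lists (vertical axis) in each library against day of pregnancy, with numbered points for libraries, a bar at the mean and a line of 1 SD to each side. Interferon-stimulated genes have a mean of 3.47 on day 14 and 4.77 on day 20, and cell cycle genes 2.18 on day 14 and 1.66 on day 23.

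From day 17 to day 20, interferon-stimulated genes had positive values in 42 of 42 members and 17 passed over the list alone. Among them were MX2 (7.91 ± 5.53 against 1.93 ± 1.34 RPKM), EIF2AK2 (14.7 ± 1.89 against 9.43 ± 2.24), IFIH1 (12.7 ± 3.39 against 7.04 ± 2.67) and STAT2 (44.3 ± 5.65 against 22.1 ± 14.1; camera adjusted p = 6.9e-28, and 0.44 with an estimated correlation). Immediate early genes, which respond within minutes to a stimulus, were positive in 24 of 28 with BTG2 past the threshold over the list alone (91.0 ± 50.1 against 29.0 ± 7.45; 1.4e-10, and 0.44 with an estimated correlation). Macrophage markers were positive in 14 of 15 (C1QC 139 ± 24.1 against 107 ± 49.3; 3.1e-07, and 0.45 with an estimated correlation) and antigen presentation in 27 of 27 (4.6e-07 and 0.45), with 0 past the threshold. Without day 17 replicate 2 the macrophage mean of 0.42 was 0.19. Negative were 45 of 45 ribosomal proteins (RPL37 1073 ± 127.5 against 1133 ± 165; 1.5e-05, and 0.80 with an estimated correlation), 19 of 19 endothelial markers (RAMP2 100.4 ± 7.80 against 113 ± 8.58; 0.00078 and 0.55) and 32 of 34 genes of oxidative phosphorylation (ATP5F1B 547.5 ± 36.95 against 613 ± 46.9; 0.0018 and 0.80), with 0 past the threshold. The ribosomal call ended without day 17 replicate 1 or day 20 replicate 1 (0.089 and 0.051), the endothelial one without day 17 replicate 2 (0.058) and that of oxidative phosphorylation without day 17 replicate 1 or 3 (0.32 and 0.18). Without day 17 replicate 4 the mean of oxidative phosphorylation was -0.17 instead of -0.09. Camera also called cytokines (0.00013), the unfolded protein response (0.0013), WNT and TGF-beta signalling (0.014) and lymphatic markers (0.022) with positive values, none of them with an estimated correlation (adjusted p = 0.45, 0.45, 0.79 and 0.46). The WNT call ended without day 17 replicate 1 or 3 (0.089 and 0.21) or day 20 replicate 1 (0.16), and the lymphatic one without day 17 replicate 1 or 2 (0.089 and 0.18) or day 20 replicate 4 (0.11). The mean of WNT genes was 0.25 instead of 0.16 without day 17 replicate 2, and that of cytokines 0.38 instead of 0.255 without day 17 replicate 3. By limma 0 genes passed, with 1091 at an unadjusted p under 0.05, 380 higher and 711 lower, a smallest adjusted p of 0.096, 0 genes and 1047 unadjusted with voom, and 81 genes and 1337 with the negative binomial test. Among the 5 with the smallest p were ANKRD33B, RGS1 (9.14 ± 3.40 against 1.86 ± 0.96), LRRC3 and the circadian gene PER1 (44.8 ± 10.4 against 19.5 ± 1.02). Without day 17 replicate 3, 1 gene passed.

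From day 20 to day 23, macrophage markers had negative values in 15 of 15 members and 6 passed over the list alone. Among them were MSR1 (2.75 ± 0.93 against 5.04 ± 0.79 RPKM), CD14 (8.21 ± 3.63 against 16.04 ± 4.92), ITGAM (1.5 ± 0.89 against 2.95 ± 0.55) and FCGR1A (3.77 ± 1.52 against 6.91 ± 1.71; camera adjusted p = 2.6e-09, and 0.29 with an estimated correlation). Cell cycle genes were negative in 28 of 30 with 9 past the threshold over the list alone (BIRC5 1.84 ± 0.43 against 2.99 ± 0.68, TOP2A 1.36 ± 0.70 against 2.89 ± 1.15, with CCNA2 and CENPF; 2.0e-12, and 0.29 with an estimated correlation). Immediate early genes were negative in 25 of 28 with 4 past it, FOSL1, BTG2, JUNB and MYC (JUNB 33.2 ± 10.1 against 91.6 ± 30.2; 7.9e-07, and 0.29 with an estimated correlation). Antigen presentation was negative in 26 of 27 with CTSS, a lysosomal protease, past it (40.3 ± 3.91 against 63.3 ± 9.27; 1.8e-08, and 0.29 with an estimated correlation). With 0 past the threshold, cytokines were negative in 25 of 26 (CXCL16 51.1 ± 4.12 against 54.3 ± 5.10; 7.8e-07, and 0.29 with an estimated correlation), apoptosis genes in 25 of 28 (3.6e-05 and 0.29) and endothelial markers in 18 of 19 (4.2e-05 and 0.40). Camera also called matrix genes (4.6e-05), pericytes (0.00016), the unfolded protein response (0.0028), angiogenesis (0.0058), WNT and TGF-beta signalling (0.0086), NF-kB signalling (0.014), ribosomal proteins (0.020) and natural killer cells (0.048) with negative values. It called antioxidant genes with positive ones (0.018). None of these held with an estimated correlation (adjusted p from 0.40 to 0.77), and those of matrix, unfolded protein response, WNT, NF-kB, ribosomal, natural killer and antioxidant genes ended with at least 1 library left out. Interferon-stimulated genes were negative in 35 of 42 with a mean of -0.18, 0 passed, and the list was not called (adjusted p = 0.080). By limma 0 genes passed, with 935 at an unadjusted p under 0.05, 328 higher and 607 lower, a smallest adjusted p of 0.22, 0 genes and 959 unadjusted with voom, and 56 genes and 1345 with the negative binomial test. The smallest p belonged to ADGRA3, DDIT4, which is induced by stress and glucocorticoids (126 ± 28.1 against 299.4 ± 87.9), LRRC4, ID2 (34.7 ± 11.4 against 93.1 ± 31.9) and CTPS1. 1 gene passed without day 17 replicate 2 and 1 without day 20 replicate 2.

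Over the 4 days, 11 genes passed the test of a linear trend in limma, 9 that fell and 2 that rose. OXT, the oxytocin gene, which large luteal cells of ruminants express, fell (slope -0.19 ± 0.03 log2 units per day, adjusted p = 0.047). Its RPKM was 4197 ± 1206 on day 14, 2565 ± 892 on day 17, 1708 ± 556 on day 20 and 1304 ± 527.5 on day 23. HSPE1, the co-chaperonin of mitochondria, fell from 331 ± 9.81 to 293.5 ± 9.24, 263 ± 24.7 and 235 ± 7.57 (slope -0.05 ± 0.01, adjusted p = 0.0059). APOD, a lipocalin that binds lipids, rose from 86.5 ± 36.2 to 255 ± 36.7 (slope 0.19 ± 0.03, adjusted p = 0.027), and IFIT1 rose as well (slope 0.29 ± 0.05, adjusted p = 0.047). BCL6B, an endothelial transcription factor, fell from 20.3 ± 4.85 to 8.29 ± 1.43 (adjusted p = 0.027), and PCDH12, an endothelial protocadherin, from 17.6 ± 4.80 to 7.74 ± 0.39. CKB (creatine kinase B), FAM171A2, MDFI, PLOD3 and FAM167B also fell, each with adjusted p = 0.047.

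**Figure D4:**
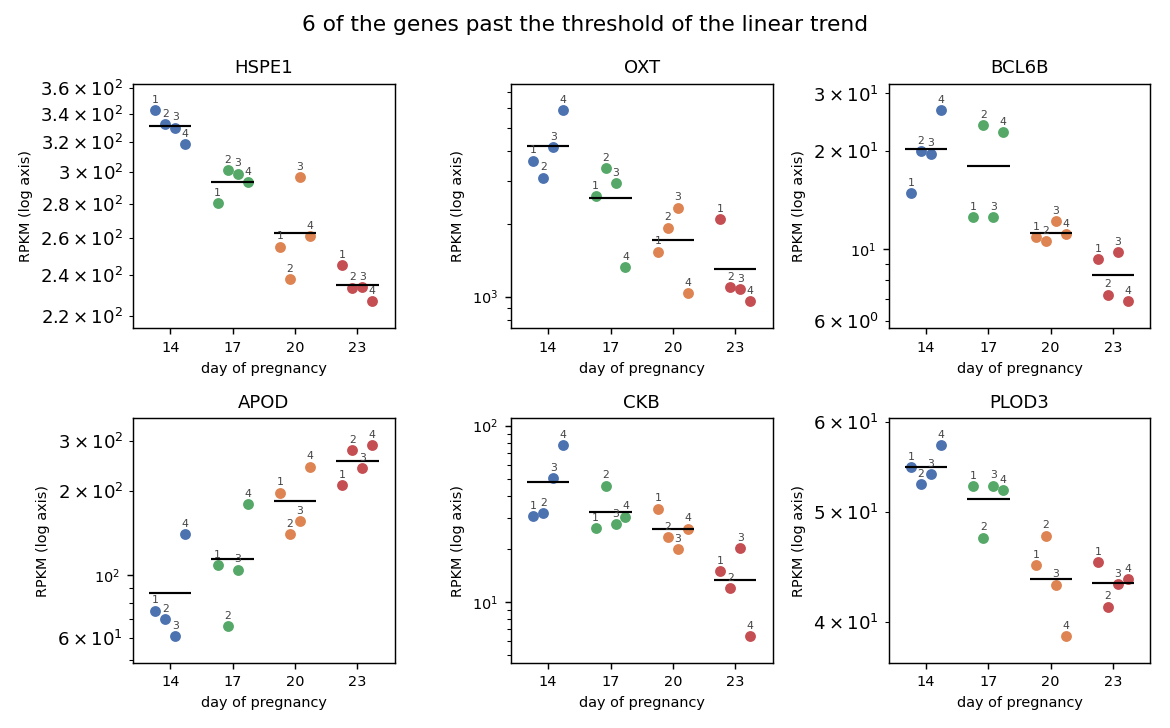
RPKM on a log axis of 6 of the 11 genes with a linear trend against day of pregnancy, with 1 numbered point per library and a bar at the mean of each day. OXT has a mean of 4197 on day 14 and 1304 on day 23, HSPE1 331 and 235, and APOD 86.5 and 255.

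There were 1760 genes at an unadjusted p under 0.05 for the trend, 547 rising and 1213 falling. Voom called 2 genes and the negative binomial test 554, the 11 among them (adjusted p from 4.7e-07 to 0.0013). HSPE1 stayed past the threshold in 27 of 27 alternatives within limma and voom, with adjusted p from 0.0022 to 0.040, whereas the other 10 lost it in some. APOD lost it in 6 of 27, BCL6B in 8, OXT, FAM167B, PCDH12 and PLOD3 in 16, MDFI in 17, IFIT1 and CKB in 18, and FAM171A2 in 15 of 26. Adjusted p ranged from 0.012 to 0.13 for OXT and from 0.010 to 0.13 for IFIT1. The count of 11 was 102 without day 14 replicate 1, 63 without day 17 replicate 3, 49 without day 23 replicate 3 and 41 without day 14 replicate 2. It was 5 without day 17 replicate 2, 4 without day 20 replicate 1, 2 or 4, 3 without day 14 replicate 4 and 2 without day 17 replicate 1. It was 1 without day 14 replicate 3, day 20 replicate 3, day 23 replicate 2 or day 23 replicate 4. The F test over the 4 days called 0 genes in limma and in voom, with 1561 and 1525 at an unadjusted p under 0.05 and a smallest adjusted p of 0.14 in limma. The negative binomial test called 716 over the 4 days. Without day 17 replicate 3 limma's F test called 22, and 1 without day 17 replicate 2 or day 23 replicate 1. By the permutation F test on list scores over the 4 days, no list passed. Its smallest p were 0.0075 for interferon-stimulated genes, 0.0096 for endothelial, 0.013 for luteal cell and 0.017 for cell cycle scores. Each of them had adjusted p = 0.13.

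The groups of 4 did not overlap for 437 genes between days 14 and 17 (3.3%), 696 between days 14 and 20 (5.2%) and 930 between days 14 and 23 (7.0%), where chance gives 2.9%. The authors' deposited column holds an adjusted p under 0.05 for 527 genes, without naming the comparison. 470 of them were tested here, 459 (97.7%) had an unadjusted p under 0.05 in the F test and 453 were among the 716 of the negative binomial test. The 527 include 29 of the 42 interferon-stimulated genes, with a deposited adjusted p of 1.5e-08 for MX2 and 0.021 for ISG15, and of 0.00034 for OXT, 2.8e-05 for HSPE1 and 1.2e-07 for EREG.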

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

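The tests of macrophage markers, of library scaling, of shared reads, of dilution by luteal cells and of a model of counts, and the negative binomial test, were chosen after the results were seen, and the others in this part before. For 73 genes and scores, each day was tested for 1 library far from the other 3 of its day, relative to the range of the 4. This was so in 18 of 292 groups (6.2%), and chance alone gives about 1 in 20.

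Of the genes, day 14 replicate 1 stood apart with a low ISG15 (RPKM 9.643, the other 3 at 23.6 to 27.5) and a high LRRC4 (1.439, others 0.629 to 0.718). Day 14 replicate 4 had a high FOS (119.3, others 9.46 to 12.2). On day 17, replicate 2 had a low ANKRD33B (0.369, others 0.752 to 0.841) and a low PLOD3 (47.46, others 52.3 to 52.75) and replicate 3 a low PGR (1.082, others 1.32 to 1.35). On day 20, replicate 2 had high MX2 (16.2, others 5.06 to 5.26) and IFIT1 (31.26, others 14.3 to 16.1), replicate 3 a high CITED4 (118.1, others 81.4 to 83.1) and replicate 4 a high PER1 (60.31, others 37.9 to 40.6). On day 23, replicate 1 had a high OXT (2090, others 957 to 1092) and replicate 3 a high HBB (1.121, others 0.039 to 0.119). Replicate 3 of day 23 also had an RPKM of 21450 for RF00002, a 5.8S ribosomal RNA gene that was chosen after its values were seen and is not in the count above, where the other 3 had 208 to 404.5.

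Of the list scores, day 14 replicate 1 stood apart with a low score of interferon-stimulated genes (3.096, others 3.55 to 3.64) and a high T cell score (1.652, others 1.05 to 1.12). Day 14 replicate 4 had a low cell cycle score (1.93, others 2.23 to 2.29) and a high score of immediate early genes (5.038, others 3.735 to 3.89). Day 17 replicate 3 had a high antigen presentation score (6.405, others 5.66 to 5.75), and whether its day in the labels is right was not tested, and day 17 replicate 2 a low antioxidant score (6.12, others 6.335 to 6.35).

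Interferon-stimulated genes had higher values on days 20 and 23 than on day 14 in 42 of 42 members, with 0 past the threshold over all genes in limma. More macrophages and monocytes as the whole cause are argued against on day 20 by a rise of the score of 1.087 (standard error 0.365) with the macrophage score as a covariate, against 1.301 (0.313) without, and on day 23 by a macrophage score that differed by -0.055 (0.251), while a part of the rise on day 20 from these cells stays open. More T and NK cells as the whole cause are argued against by a rise on day 20 of 1.237 (0.406) with their score as a covariate, against 1.301 (0.313). A part from these cells stays open, since the score rests on markers of low RPKM and may adjust for them in part only. Library scaling is argued against by 1.297 (0.31) in the smaller of the 2 scalings tried. Reads shared between near-identical copies are argued against by 1.245 (0.292) for the 38 members other than OAS1 and IFITM genes. Both stand against the same 1.301 (0.313). Open and untested is a batch, which the labels do not give. Whether the rise belongs to pregnancy or to the passing days alone cannot be told, since no nonpregnant cattle were measured. Chance is argued against, but not excluded, for the members past the threshold over the list alone. There 1 of the 35 splits of the 8 libraries, the real one, gave as many on day 20 (38, highest other 0) and 1 of 35 on day 23 (36, highest other 24). This is the smallest share that 35 splits can give, and it was not adjusted over the counts tested so. The exact permutation test on the list score had adjusted p = 0.21 on day 20 and 0.14 on day 23.

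Cell cycle genes had lower values on day 23 than on day 14 in 30 of 30 members and endothelial genes in 19 of 19, with 20 and 7 past the threshold over the list alone (1 endothelial gene without day 14 replicate 3, 3 without day 14 replicate 4 and 4 without day 23 replicate 3 or 4), 0 over all genes in limma and no call by camera with an estimated correlation. Library scaling is argued against by a difference of -0.497 in the cell cycle score (standard error 0.131) in the smaller of the 2 scalings tried, against -0.527 (0.144). Fewer endothelial cells as the whole cause of the cell cycle values are argued against weakly. The difference was -0.491 (0.209) with the endothelial score as a covariate. A part from these cells stays open, since the score may adjust for them in part only. More luteal cells diluting the others alike is argued against by the endothelial score, whose change was -0.474 (0.139) relative to the mean score of 7 other stromal and immune cell types, itself changed by 0.115 (0.102). The 7 did not move together. T cell (0.38), natural killer (0.423), lymphatic (0.209) and fibroblast scores (0.159) were higher. Dendritic (-0.244), pericyte (-0.064) and macrophage scores (-0.055) were lower. A dilution hidden by the rises stays open. Granulosa (-0.331) and epithelial and mesothelial scores (-0.454), which are not among the 7 and which camera did not call, were lower too. Fewer endothelial cells for the endothelial values and a batch stay open, untested, and pregnancy cannot be told apart from the passing days alone. Chance cannot be excluded: 2 of the 35 splits gave as many cell cycle genes past the threshold over the list alone (20, highest other 21) and 2 of 35 as many endothelial genes (7, highest other 9).

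The authors' column has 527 genes at an adjusted p under 0.05, where limma called 0 in the F test with 1561 at an unadjusted p under 0.05 and voom 0 with 1525. A negative binomial test on the recovered reads over the 4 days called 716 genes, with 96.4% of the 470 of the column tested here among them. Its p had a rank correlation of 0.993 with the column (limma 0.917, voom 0.971), so that the column is close to such a test. Counts alone do not account for the gap, since voom on the same reads called 0. What else in the negative binomial test does was not tested. Calls among low genes account for few of the 527, since 10.8% of them were below the filter. A library far from the other 3 of its day stood in 18.3% of the called genes, against 18.8% of the 12891 others. By this rule the called genes had such a library about as often. Whether calls rest on 1 library is not decided, since the rule can miss a library that matters. It did not flag day 17 replicate 3 for ISG15 (RPKM 359.5, others 26.8, 28.4 and 61.3). Which comparison and model the column holds is not given, which of its calls are false stays open, and no biological explanation was tested. The 27.6% of false calls on simulated reads belongs to the negative binomial test used here. No such share was measured for the column.

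For counts over all genes, splits of the same libraries argue against chance in some comparisons. They do not exclude it, since 1 of 35 is the smallest share that 35 splits can give. No share was adjusted over the counts tested so. Chance is argued against for genes at an unadjusted p under 0.05 on day 23 against day 14 (1 of the 35 splits gave as many, 1679, highest other 1574). It is too for the genes called with only the 8 libraries on day 20 (1 of 35, 20, highest other 3) and on day 23 (1 of 35, 13, highest other 4). In 100 drawn regroupings it is argued against for the F test (2 of 100, 1561, highest other 1661) and the trend (1 of 100, 1760, highest other 1509). For the 11 genes called for the trend, 2 of 100 gave as many, but the highest other gave 47, several times the real count. With 1 library left out the real count itself ranged from 1 to 102. No conclusion on chance is drawn for it, and why a regrouping gave 47 was not tested. Chance is not argued against for the unadjusted counts on day 17 against day 14 (9 of 35 splits, 1011, highest other 2206) and day 20 against day 14 (4 of 35, 1084, highest other 1724). The same holds for day 20 against day 17 (6 of 35, 1091, highest other 1477) and day 23 against day 20 (5 of 35, 935, highest other 1390). Nor is chance argued against for the lists called by camera with its preset correlation, on day 17 (29 of 35, 7, highest other 19), day 20 (4 of 35, 14, highest other 18) and day 23 (14 of 35, 10, highest other 21). For genes called by the negative binomial test, chance is argued against on day 23 against day 14 (1 of 35 splits, 518, highest other 253) and for the trend (1 of 100 regroupings, 554, highest other 307). Over the 4 days it is so by a narrow margin only (1 of 100, 716, highest other 709). Chance is not argued against on day 17 against day 14 (16 of 35, 21, highest other 733), day 20 against day 14 (2 of 35, 188, highest other 405), day 20 against day 17 (4 of 35, 81, highest other 114) and day 23 against day 20 (4 of 35, 56, highest other 192). The 733 and the 192 are several times the real counts, for a reason that was not tested.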

How the results depend on the processing

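Voom, the negative binomial test, the robust spread, single lists with each library left out, 2 list scores without some members and the counts over a list alone under alternatives were chosen after the data were seen, and the other alternatives before. The counts of genes changed most under the negative binomial test on the recovered reads, which used median-ratio scaling. It called 21 genes on day 17, 188 on day 20 and 518 on day 23 against day 14, 81 on day 20 against day 17, 56 on day 23 against day 20, 716 over the 4 days and 554 for the trend, against 0, 0, 0, 0, 0, 0 and 11. For the trend, voom on the same reads called 2 genes and limma with median-ratio scaling 3, and in the other comparisons both called 0. For single named genes, with that test left out, 1782 of 2042 values under alternatives kept their direction and side of the threshold and moved by at most 1 standard error. The others were 146 weaker, 51 stronger, 61 moved and 2 reversed. Of the values that moved or reversed, 26 values in 12 results changed sign. Many of the 2042 values could not move, so the share that stayed does not measure how stable the fold changes are. For a contrast, leaving out a library of another day or changing the filter keeps the fold change. So do the replicate block, no intensity trend and the robust spread. These alternatives can alter only its standard error and p. Depth limits low genes most, as 1 read per kilobase is an RPKM of about 0.0264. For the values below, the cause was not tested, except that fewer members are tested under the filter on a mean RPKM of 5 and that the 8 libraries of 2 days leave out the spread of the other days.

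The 0 genes of day 20 against day 14 became 1 with a pseudocount of 0.1 and 20 with only the 8 libraries. The 0 of day 23 against day 14 became 2 with no filter, 2 with a mean RPKM of at least 5, 4 with array weights, 1 with the robust spread and 13 with only the 8 libraries. The 11 trend genes became 37 with a pseudocount of 0.5, 1 with no filter, 43 with a mean RPKM of at least 5, 3 with median-ratio scaling, 39 with quantile normalization, 47 with array weights, 4 with no intensity trend, 2 with voom and 3 with the robust spread. With an estimated correlation, 0, 0 and 0 lists were called on days 17, 20 and 23. A mean RPKM of at least 5 left 1 of 20 cell cycle genes on day 23 and 0 of 5 natural killer genes on day 17, where only the 8 libraries gave 3. HSD3B1 on day 23 reversed to -0.0468 from 0.26 under quantile normalization.

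Replicate numbers do not pair the cattle: 5 of 24 paired correlations were above 0.1 (range -0.226 to 0.211), and 3 of 16 libraries correlated best with their own number. With a replicate block, 2 genes passed on day 23 against day 14 and 2 for the trend.

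With 1 library left out, genes called ranged from 0 to 1 (without day 17 replicate 3) on day 17, 0 to 32 (without day 17 replicate 3) on day 20 and 0 to 22 (without day 17 replicate 3) on day 23 against day 14. They ranged from 0 to 1 for day 20 against day 17, 0 to 1 for day 23 against day 20, 0 to 22 for the F test and 1 to 102 for the trend (without day 14 replicate 3 and replicate 1). Lists ranged from 7 to 14 on day 17, 10 to 17 on day 20 and 8 to 13 on day 23. Members past the threshold over the list alone ranged from 36 to 39 (interferon, day 20), 24 to 37 (interferon, day 23), 17 to 22 (cell cycle), 1 to 9 (endothelial) and 2 to 6 (natural killer). The FOS day 23 vs day 14 log2 fold change ranged from -1.24 without day 23 replicate 3 to 0.25 without day 14 replicate 4, a reversal.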

Other observations

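The genes of this part were chosen after their values were seen, from lists that camera did not call, because they passed when adjusted over their list alone. None passed over all genes by limma in the model of 16 libraries. On day 23, TNFAIP6 and FOSL1 did with only the 8 libraries of days 14 and 23 (adjusted p = 0.033 and 0.040), and FOSL1 without day 17 replicate 3 (0.036). Among luteal hormones and receptors, IGFBP6 was at an RPKM of 98.15 ± 7.93 on day 17 against 65.7 ± 11.3 on day 14 (SD, n = 4), and FST, the activin-binding follistatin, at 185.5 ± 106 on day 23 against 69.2 ± 25.01. TNFAIP6, a hyaluronan-binding protein of the ovulating follicle, was at 33.7 ± 9.03 on day 14, 15.6 ± 9.34 on day 17, 14.0 ± 5.12 on day 20 and 8.585 ± 1.31 on day 23. FOXL2, a granulosa transcription factor, was at 26.1 ± 3.26 on day 20 against 35.6 ± 3.15 on day 14.

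On day 23 against day 14, the keratins KRT8 and KRT18 were at 20.6 ± 8.33 against 41.5 ± 6.82 and at 2.04 ± 1.33 against 6.68 ± 2.45. NOS2 was at 2.85 ± 0.63 against 6.29 ± 1.775, the apoptosis gene BAK1 at 24.6 ± 1.74 against 33.3 ± 4.11, and the pericyte genes CSPG4 and KCNJ8 at 5.14 ± 0.57 against 8.41 ± 1.26 and 16.02 ± 1.73 against 22.6 ± 4.71. Higher on day 23 were ADM, the vasodilator adrenomedullin, at 247 ± 32.1 against 119 ± 33.4, PDPN (podoplanin) at 163 ± 65.0 against 88.9 ± 21.4 and WNT2B at 16.1 ± 6.445 against 8.39 ± 2.40. LEF1 was at 1.76 ± 0.28 against 4.76 ± 1.78 and FOSL1 at 1.10 ± 0.22 against 3.65 ± 0.64.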
